A study of Mus musculus with 2 samples.

How the data were processed

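Pancreatic islet cells of C57BL/6J mice, a common inbred strain, were profiled by droplet single-cell RNA sequencing after the mice had received regular chow or a 60% high-fat diet (HFD) from weaning on, for 6 weeks. Per the labels, islets of 4 chow mice and 5 HFD mice were picked by hand, kept in culture overnight, dispersed with 0.05% trypsin in 10 minutes and strained through a 35 µm mesh, and viability above 95% and doublets under 5% are stated. Libraries were made with the 10x Genomics 3' v2 chemistry, which counts unique molecular identifiers (UMIs) at the 3' end of polyadenylated RNA. Each diet has 1 library, and no source used here ties a cell to a mouse.

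The deposited matrices hold whole-number UMI counts per gene and barcode, without normalization, per the labels and the values themselves. The reads were processed with Cell Ranger 2.1.0, per the submitters' processing notes. The genome build, the annotation and the rule by which barcodes were kept as cells are not given in the sources used here, so no coordinates are printed. The smallest barcode held 3846 UMIs in the chow library and 4017 in the HFD library, which places the floor for a cell near the same value in both. The gene table lists 27998 genes with Ensembl identifiers and symbols, both printed as the files give them.

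From these counts, barcodes with under 500 detected genes or over 10% mitochondrial UMIs were removed, 122 in the chow library and 145 in the HFD library. Doublets were scored per library with Scrublet as provided in scanpy 1.11.5. Its automatic threshold marked 0.0939% and 0.0228% of barcodes and so had not worked. The fallback set for that case, removal of scores above the threshold that leaves the top 5%, took out 290 further barcodes (4.54%) in the chow library and 175 (3.98%) in the HFD library, with tied scores at the threshold kept. The 6097 chow and 4219 HFD cells kept were scaled to 10000 UMIs per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 (igraph 0.11.9) on both libraries together gave 19 clusters. No batch integration was applied, since the library and the diet are the same split.

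Clusters were named from markers of 16 cell classes. 3 marker symbols are not in the gene table. A marker counted as detected from 0.1 counts per 10000, its level was set against its mean over the 10 cells with the highest value, and the class with the highest mean score was taken. Where another class reached 0.8 of the best score, the class with more markers among the 10 genes leading the cluster by fold was used. The markers were fixed in advance, but this scoring rule was set after the clusters had been seen: a first form called clusters with little acinar RNA acinar, and a second left the somatostatin cluster without a name. Clusters with under 3 detected markers, with more leading markers of another class, or of low depth with no leading marker were to stay unnamed, and none of the 19 met these conditions. Names are written as "beta-like" and so on, since they rest on rebuilt clusters.

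Counts were summed over the cells of a type in each library and expressed as counts per 1000000 UMIs of that type (CPM), with exact Poisson 95% intervals. The log2 ratio of HFD over chow was taken with 0.5 counts added to each sum. Shares of cells have exact Clopper-Pearson 95% intervals. Where no cell met a rule, the limit given is that of 3 cells in place of 0, which is narrower than the upper end of the two-sided exact interval. All of these intervals cover counting error only. With 1 library per diet there is no replicate check, no test of diet was made, and no p-value, standard error or count of changed genes is given: each statement describes the 2 libraries. Types with at least 50 cells in both libraries were compared, which left 6 types.

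For each of 25 gene lists, the median log2 ratio over members with a summed count of at least 50 was placed among the medians of 10000 random lists of the same size, matched on mean expression in 25 bins. A list below percentile 2.5 or above percentile 97.5 is said to stand apart, as a description of these libraries. The difference between the list's median and the median of those random lists, called the list difference here, does not depend on the scaling. Counts of alternatives under which a list of HFD against chow kept its call include those that change the scaling only. These could hardly move such a call. Members' counts above or below are set against the median ratio of all genes of the type.

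Named genes followed a rule. Predicted genes, pseudogenes and mitochondrial RNA genes were left out, as were markers of other classes in beta-like cells. The 12 highest and 12 lowest log2 ratios were taken among genes with at least 20 CPM in 1 library in beta-like cells, and the 5 highest and 5 lowest among genes with at least 50 CPM and a summed count of at least 100 in each other type. Of each list, members with the highest expression or the largest ratios were named. Some members that this rule would name are not reported here. Ins1, Ins2, Iapp, Gcg, Sst, Ppy, Cd63, Mafa, Ucn3, Slc2a2, Aldh1a3, Cck, Gast, Tph1, Tph2, Txnip and Mki67 were always considered.

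For the Cd63 comparison, each beta-like cell was thinned at random to 4000 UMIs with seed 7, and the 24 chow cells below that depth were left out. Cells at or above the 75th percentile of thinned Cd63 counts in the chow library, 5 counts, were called Cd63-high, and those at or below the 25th percentile, 1 count, Cd63-low. The same counts were applied to the HFD library. High and low cells were summed and compared within each library, and the same split was repeated on 100 control genes of the nearest mean expression over both libraries. Named genes were the 12 highest and 12 lowest by the mean of both libraries' ratios, among genes with at least 50 CPM and the same sign in both. Cycling cells were those with UMIs of at least 2 of 12 mitotic genes at 4000 UMIs.

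The groups, the types of result, the gene lists, the markers, the rule for named genes and the list of alternatives were fixed before the data were examined. The alternatives were a looser and a stricter cell filter, no removal of doublets, Leiden resolutions of 0.5 and 2.0, clustering of each library on its own, TMM factors (edgeR 4.0.16), median-of-ratios factors (DESeq2 1.42.0), totals without 7 hormone genes, means over cells, thinning, other minimum counts and subtraction of free RNA. edgeR and DESeq2 served as scalings only. Alternatives chosen after seeing the data left out the Ppy-bearing clusters (6 and 13, the latter also led by interferon genes) or the interferon and cell cycle clusters (13 and 15), used 1 shared beta-like cluster alone (cluster 0, which has the most cells in its smaller library), looked within single clusters, or repeated the thinning with another draw.

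The ratio step was tested on simulated Poisson counts with the summed profile and depths of beta-like cells, without spread between cells or mice. This checks the calculation only. Of 100 genes changed 1.5-fold and 100 changed 2-fold among 12161 genes, 100 and 100 came out in the right direction, and the 95% interval held the true ratio for 93% and 95% of them. On the real ratios, among random lists of 20 genes drawn from 12149 genes, 2.5% stood apart with no shift, 72% with a shift of 0.2 and 99.5% with a shift of 0.4 in log2. Fewer matched lists were drawn for this check than for the results. Members were drawn independently, so it does not show how often lists of genes that vary together stand apart. Further tools were Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3.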

Results

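Pancreatic islets hold the cells that secrete insulin (beta cells), glucagon (alpha cells), somatostatin (delta cells) and pancreatic polypeptide (PP cells), along with blood vessel cells and resident macrophages. A diet rich in fat raises the demand for insulin, and the study asked how beta cells that differ in the tetraspanin CD63, a membrane protein of endosomes, lysosomes and secretory vesicles, fare under such a diet. Islet cells of C57BL/6J mice were profiled by droplet single-cell RNA sequencing in 1 library from 4 mice on regular chow and 1 library from 5 mice on a 60% high-fat diet (HFD). The chow library held 6509 barcodes with 89292222 UMIs, a median of 12414 UMIs and 2358 genes per barcode. The HFD library held 4539 barcodes with 68544729 UMIs, a median of 13911 UMIs and 2663 genes. Mitochondrial UMIs made up a median of 2.96% in the chow library and 3.07% in the HFD library. After removal of low-quality barcodes and called doublets, 6097 chow cells and 4219 HFD cells were compared. Intervals throughout are 95% and cover counting error only; there are no replicates, and differences are stated as differences between these 2 libraries.

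The make-up of an islet can shift with diet, since beta cells may multiply when insulin demand is high and immune cells may enter inflamed tissue. Islet cells were named by their hormone or marker genes: Ins1 and Ins2 encode insulin, Gcg encodes glucagon, Sst somatostatin and Ppy pancreatic polypeptide. Beta-like cells formed 72.0% of chow cells (4391 cells, Clopper-Pearson interval 70.9 to 73.1%) and 71.0% of HFD cells (2994 cells, 69.6 to 72.3%), with overlapping intervals. With each library clustered on its own they formed 71.8% (70.7 to 72.9%) and 63.8% (62.4 to 65.3%), where a cluster of 298 HFD cells with the highest score for beta cells stayed unnamed because of a PP marker among its leading genes. Alpha-like cells made up 11.9% (725 cells, 11.1 to 12.7%) in the chow library and 9.22% (389 cells, 8.36 to 10.1%) in the HFD library. Delta-like cells were more frequent in the HFD library, 9.55% (403 cells, 8.68 to 10.5%) against 7.74% (472 cells, 7.08 to 8.44%). PP-like cells accounted for 3.08% of chow cells (188 cells, 2.66 to 3.55%) and 3.27% of HFD cells (138 cells, 2.75 to 3.85%), and endothelial-like cells for 3.0% (183 cells, 2.59 to 3.46%) and 2.96% (125 cells, 2.47 to 3.52%). Macrophage-like cells made up 0.984% of chow cells (60 cells, 0.752 to 1.26%) and 1.75% of HFD cells (74 cells, 1.38 to 2.20%). Fibroblast-like cells, led by Mgp, Igfbp5, Bgn, Des and Pdgfrb, made up 0.705% (43 cells, 0.511 to 0.949%) and 1.47% (62 cells, 1.13 to 1.88%). This name is uncertain, since the fibroblast score was 0.151 against 0.117 for pericytes, and Pdgfrb, the 1 fibroblast marker among the 10 leading genes, is also a gene of pericytes. Schwann-like cells numbered 18 and 14, ductal-like cells 8 and 19, and acinar-like cells 9 and 1. These shares depend on which droplets were kept as cells: the smallest barcode held 3846 UMIs in the chow library and 4017 in the HFD library, while median depth was 14534 and 16502 UMIs in beta-like cells but 8322 and 10840 in alpha-like and 8014 and 9604 in delta-like cells.

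Beta cells were spread over several clusters that the libraries filled unequally. In the chow library most beta-like cells lay in cluster 5 (998 cells), which was led by Fam151a and the heat shock gene Hspa1a, and in clusters 0 (751 cells), 1 (646 cells), 3 (635 cells) and 8 (498 cells). Cluster 0 was led by the glucose transporter gene Slc2a2 with Ppp1r1a and Ero1lb, cluster 1 by Ppp1r1a, Ins2 and Ucn3, cluster 3 by Cox6a2, Prlr and Prss53, and cluster 8 by the opioid peptide gene Pdyn with Crybb3 and Fkbp11. In the HFD library they lay in cluster 2 (1325 cells), led by Mlxipl, which encodes the glucose-sensing factor ChREBP, with Insrr and Slc2a2, and in clusters 0 (649 cells) and 6 (389 cells). Cluster 6, led by Txnip and Fxyd6, also carried Ppy, as did cluster 13. Cluster 5 held 22.7% of chow and 0.802% of HFD beta-like cells, and cluster 2 held 6.26% and 44.3%. Cluster 7, led by the metallothionein genes Mt1 and Mt2, held 6.10% and 7.35%. The small clusters 13, led by the interferon-induced genes Irf7, Ifit1, Ifit3 and Rsad2, and 15, led by the cell cycle genes Ube2c, Top2a and Cenpf, held 53 and 13 chow cells and 17 and 10 HFD cells.

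Under a high-fat diet beta cells have to make and fold more proinsulin while taking up more fuel, and the genes of protein folding, glucose sensing and stress defence are those first looked at. Counts of all beta-like cells were summed in each library and compared as CPM, with the log2 ratio of HFD over chow. The median of this ratio over 12149 genes was 0.19, against 0.0091 with TMM and 0.00021 with median-of-ratios factors, so ratios of beta-like cells are given relative to that median. Hspa1a (ENSMUSG00000091971), which encodes an inducible chaperone of the cytosol, had 62.8 CPM (Poisson interval 61.0 to 64.8) in the chow library and 4.86 CPM (4.27 to 5.52) in the HFD library, a relative log2 ratio of -3.88. Its near-identical copy Hspa1b stood at -3.78, and since short reads cannot always be assigned between the copies, each value alone is uncertain. The chaperone partner gene Dnajb1 stood at -1.75 (45.7 and 15.5 CPM). Cd63 (ENSMUSG00000025351) had 899 CPM (892 to 906) in the chow library and 305 CPM (301 to 310) in the HFD library, 2.94 times as much in the chow library, with a relative log2 ratio of -1.75. Fkbp11, a proline isomerase gene, had 41.7 and 8.90 CPM (-2.42), and Sdf2l1, a chaperone gene of the unfolded protein response, had 97.4 and 39.6 CPM (-1.49). Cox6a2, which encodes a cytochrome c oxidase subunit typical of muscle, had 51.7 and 13.7 CPM (-2.11), the glutathione transferase gene Gstp1 had 21.8 and 5.69 CPM (-2.13), and the interferon-induced Ifi27 had 65.2 and 21.6 CPM (-1.78). Crybb3 (242 and 88.0 CPM, -1.65), which encodes a crystallin, the tubulin gene Tubb3 (-1.63) and the uridine phosphorylase gene Upp1 (-1.54) completed the group with the lowest ratios, apart from Lcn2. For Lcn2, which encodes the iron-binding secreted protein lipocalin 2, the relative ratio was -5.10 (37.4 and 1.23 CPM), but 5 cells held 46.2% of the chow counts and 151 chow cells had any.

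Txnip encodes a thioredoxin-binding protein that is induced by glucose and restrains glucose uptake. Txnip (ENSMUSG00000038393) was higher in the HFD library, 142 CPM (139 to 146) against 67.6 CPM (65.6 to 69.6) in beta-like cells, a relative log2 ratio of 0.88. Other genes with the highest ratios were Gatm (18.2 and 37.7 CPM, 0.86), which encodes the first enzyme of creatine synthesis, the calcium channel gene Itpr1 of the endoplasmic reticulum (12.3 and 24.9 CPM, 0.83) and Pdcd4, a brake on translation (79.2 and 147 CPM, 0.71). The cell cycle inhibitor gene Cdkn1b had 15.2 and 28.0 CPM (0.69), the methyltransferase gene Setd7 20.3 and 37.4 CPM (0.69) and the cyclin-dependent kinase gene Cdk14 10.9 and 22.2 CPM (0.84). Ubxn2a (0.83), Dbpht2 (0.84), Zfos1 (0.69) and the noncoding Snhg11 (0.90) were higher as well. The mitochondrial gene mt-Nd4l stood at 0.69, but it overlaps mt-Nd4 and its reads may be shared. In the 5 clusters with at least 100 beta-like cells in each library (0, 2, 3, 6 and 7), Cd63 was lower in the HFD library in 5 of 5, with relative ratios from -1.08 to -0.29, and Txnip was higher in 5 of 5 (0.39 to 0.64). Hspa1a (-4.60 to -1.60), Fkbp11 (-1.50 to -0.63), Gstp1 (-1.74 to -1.04) and Ifi27 (-1.94 to -1.04) were likewise lower in 5 of 5 clusters. Clusters 1, 5 and 8, with 14.7%, 22.7% and 11.3% of chow but 1.87%, 0.802% and 0.534% of HFD beta-like cells, are not covered by these comparisons.

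**Figure D1:**
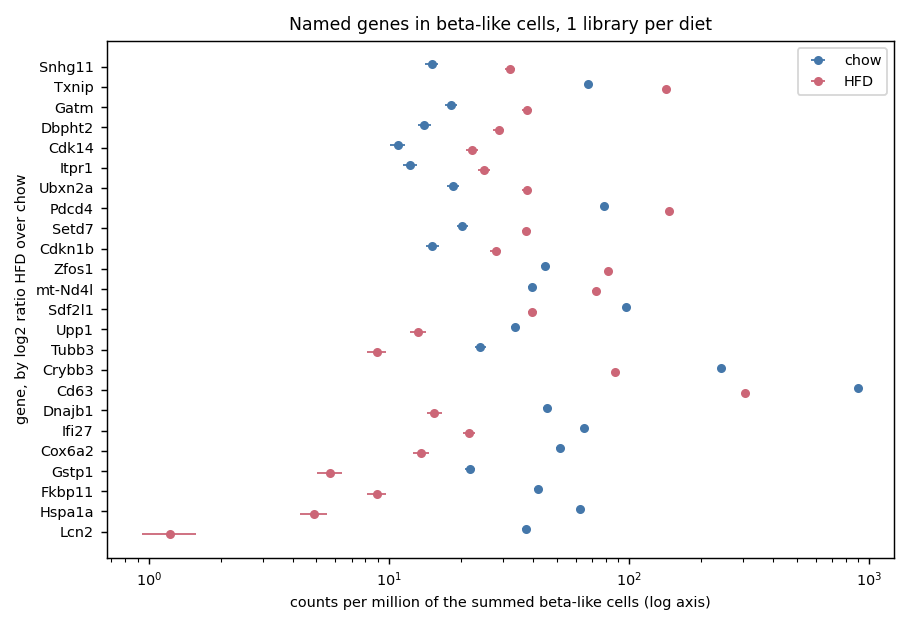
Counts per 1000000 UMIs (CPM), on a log axis, of the 24 genes with the lowest and highest HFD over chow ratios in beta-like cells, with 1 marker per library and horizontal bars for exact Poisson 95% intervals. Cd63 stood at 899 CPM in the chow library and 305 CPM in the HFD library, and Txnip at 67.6 and 142 CPM.

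The hormone genes themselves take most of a beta cell's messenger RNA, and mature beta cells also express Ucn3, Slc2a2 and Mafa. Ins2 had 363120 CPM in chow and 335830 CPM in HFD beta-like cells (relative log2 ratio -0.30), and Ins1 had 160660 and 196780 CPM (0.10). Iapp, which encodes the co-secreted amyloid polypeptide, had 77350 and 62102 CPM (-0.51). Ucn3, which encodes the peptide urocortin 3 of mature beta cells, had 251 and 218 CPM (-0.39), and Slc2a2 had 78.6 and 92.7 CPM (0.05). In cluster 0, with 751 chow and 649 HFD cells the shared cluster with the most cells in its smaller library, the ratios of Ins2 and Slc2a2 before subtraction of the median took the other sign, 0.08 and -0.16. Hormones of other cells were present as well, with Gcg at 1013 and 650 CPM (-0.83), Sst at 224 and 176 CPM (-0.54) and Ppy at 2790 and 3614 CPM (0.18). The sums of Ppy include the Ppy-bearing cluster 6, with 5.78% of chow and 13% of HFD beta-like cells, and the median cell at 4000 UMIs had 5 Ppy UMIs in the chow and 4 in the HFD library. Mafa was counted 5 and 4 times, the dedifferentiation gene Aldh1a3 9 and 11 times, the gut hormone genes Cck 12 and 10 times and Gast 54 and 44 times, and the proliferation gene Mki67 35 and 34 times. The genes for serotonin synthesis, Tph1 (1 and 0 counts) and Tph2 (89 and 62 counts), were as scarce, and a difference was not detectable at this depth for any of these 7 genes.

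Oxidative phosphorylation turns glucose into the ATP that triggers insulin release, and its nuclear and mitochondrial genes are transcribed from separate genomes. The unfolded protein response relieves the secretory pathway, and interferon raises antigen presentation. Of 25 gene lists in beta-like cells, 4 stood apart below and 3 above random lists of like expression, as a description of these libraries. For the 76 nuclear-encoded genes of oxidative phosphorylation, 0 lay above the all-gene median and 76 below, with a list difference of -0.42 (percentile 0.00). Cox5a had 127 and 60.3 CPM (relative log2 ratio -1.27), Ndufb6 85.5 and 41.1 CPM (-1.25) and the abundant Cox8a 799 and 716 CPM (-0.35). The unfolded protein response list (24 of 26 genes below) had a list difference of -0.32 (percentile 0.06), with Manf, a secreted survival factor of the endoplasmic reticulum, at 300 and 129 CPM (-1.41), the calreticulin gene Calr at 251 and 163 CPM (-0.81) and the chaperone gene Hspa5 at 246 and 200 CPM (-0.48). Both lists kept their call under 16 of 16 alternatives, although those that change the scaling only could hardly move it. They stood apart below in 5 of 5 shared clusters, though at a smaller median of -0.16 and -0.18. The shared clusters leave out clusters 1, 5 and 8, which held many chow but few HFD beta-like cells. The interferon and antigen presentation list (17 of 20 below) stood at -0.54 (percentile 0.00), with B2m, the light chain of class I molecules, at 93.3 and 45.4 CPM (-1.23), while Irf1 was higher in the HFD library (0.29). Glycolysis (11 of 13 below) stood at -0.48 (percentile 0.08), with Aldoa at 261 and 161 CPM (-0.89), Pkm at 263 and 216 CPM (-0.47) and Gapdh at -1.48, the last uncertain because of its many pseudogenes. In cluster 0 alone the interferon list (-0.14) and glycolysis (0.01) no longer stood apart, and over the 5 shared clusters they did so in 1 and 2.

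Ribosomal proteins build the translation machinery, and genes of the Y chromosome serve as a check of library make-up. Among lists higher in the HFD library, ribosomal protein genes stood at 0.13 (percentile 99.6) in beta-like cells, although 67 of 94 lay below the all-gene median, since random lists of like expression lay lower still. Rps27 (779 and 1343 CPM, relative log2 ratio 0.60) and Rps29 (794 and 1254 CPM, 0.47) were higher and Rplp1 lower (-0.30). The 13 mitochondrially encoded genes were divided, 7 above and 6 below, with a list difference of 0.28 (percentile 98.5); mt-Nd3 had 297 and 483 CPM (0.51) and mt-Cytb stood at -0.19. This list ended within cluster 0 (0.05) and with cells thinned to equal depth (0.20). The sex-linked list (4 of 4 above) stood at 0.32 (percentile 99.2), with Ddx3y at 29.4 and 38.4 CPM (0.19) and Eif2s3y at 21.9 and 33.3 CPM (0.41), and it ended within cluster 0 (0.10) and with no minimum count (0.24). Of the 5 shared clusters, ribosomal proteins stood apart above in 4, the mitochondrially encoded list in 1 and the sex-linked list in 2. Xist had 10 and 7 counts.

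Beta cell identity rests on transcription factors, while immature or stressed beta cells take up genes that are normally silent in them. In beta-like cells the beta cell identity and maturity list stood at 0.19 (percentile 97.1), just within the range of random lists, with Pax6 (152 and 254 CPM, relative log2 ratio 0.55), Rfx6 (0.48) and Foxa2 (0.43) above and the prohormone convertase gene Pcsk1 below (-0.73). The dedifferentiation list stood at -0.22 (percentile 12.2), although the progenitor factor gene Neurog3 had 0.551 CPM in the chow library and 2.52 CPM in the HFD library (1.99). Fatty acid oxidation and lipid load stood at 0.13 (percentile 95.2), with the carnitine transferase gene Cpt1a at 6.36 and 14.1 CPM (0.96) and the uncoupling protein gene Ucp2 at 158 and 246 CPM (0.45). Fatty acid synthesis (-0.24, percentile 6.76), cholesterol synthesis (-0.14, 4.6) and the tricarboxylic acid cycle (-0.14, 10.7) were within the range of random lists, as were antioxidant genes (-0.13, 12.2) with Txn1 at -1.12. The list of immediate early and heat shock genes (-0.16, 8.14) had Fos (281 and 448 CPM, 0.48) and Egr1 (106 and 180 CPM, 0.58) above and the chaperone gene Hspa8 below (-0.85), while 5 of 13 immediate early members lay above the all-gene median and their median was -0.17. Within the 5 shared clusters the sign of this list turned, with list differences of 0.03 to 0.48 (median 0.13), and it stood apart above in 1. Secretory granule and exocytosis genes stood at 0.10 (85.2), with Cplx2 at 0.64 and Vgf at -1.49, and beta cell heterogeneity genes at -0.21 (5.70), with the neuropeptide gene Npy at -2.31. Lists of the lysosome and tetraspanins (-0.07, 25), inflammatory cytokines (-0.02, 46.1), the cell cycle (-0.18, 7.23), lipid-associated macrophages (-0.21, 9.24) and extracellular matrix (-0.18, 18.2) did not stand apart. Neither did the identity lists of alpha (0.02, 55.8), delta (-0.38, 7.21) and endothelial cells (-0.21, 10.9). Within the 5 shared clusters, however, delta identity stood apart below in 4 (median -0.36) and heterogeneity genes in 3 (-0.27). The delta list had only 4 measured genes in each of these clusters, and its genes Isl1 and Pcsk1 are also on the beta cell identity list. Fatty acid oxidation stood apart above in 2 of the 5 shared clusters, and cholesterol synthesis below in 1 and above in 2.

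**Figure D2:**
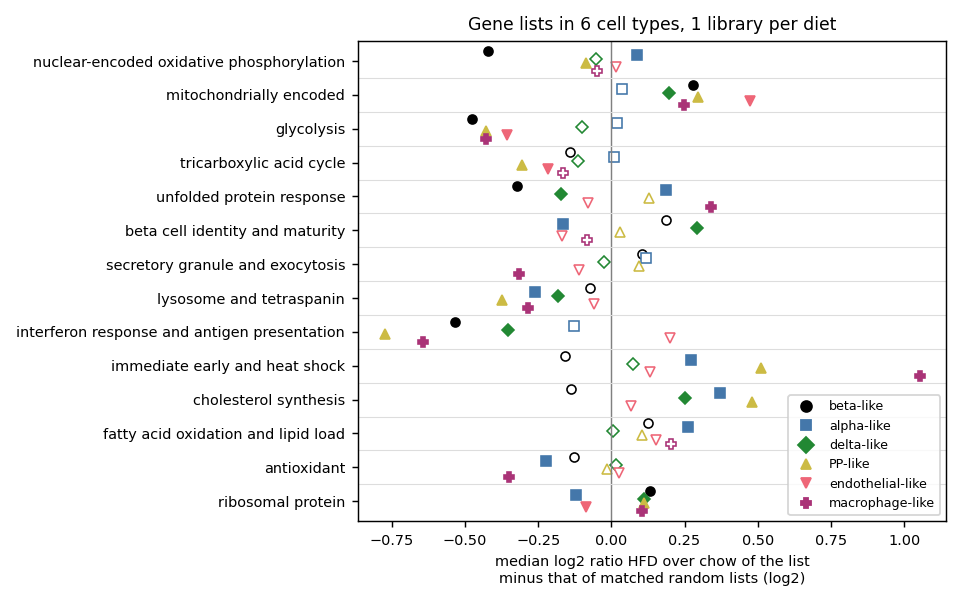
Median log2 ratio of HFD over chow of 14 gene lists minus that of matched random lists, in 6 cell types, with filled markers for lists outside the central 95% of random lists and open markers for the rest. Nuclear-encoded oxidative phosphorylation stood at -0.42 in beta-like and 0.09 in alpha-like cells.

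Alpha cells release glucagon and share many genes of secretion with beta cells. The question put to the other cell types was whether their libraries differed in the same genes. Ratios of these types are given without subtraction, since their all-gene medians lay within 0.1 of 0. In alpha-like cells 9 of 22 lists stood apart. Gcg had a log2 ratio of 0.13. Cholesterol synthesis stood at 0.37 (percentile 100; 20 of 23 genes above), with the sterol oxidase gene Msmo1 at 35.6 and 73.9 CPM (1.05). The unfolded protein response was higher in the HFD library in alpha-like cells (0.19, percentile 99.8), with Hsp90b1 at 222 and 327 CPM, and so were fatty acid oxidation (0.26, 99.6), nuclear-encoded oxidative phosphorylation (0.09, 99.5) and the immediate early and heat shock list (0.27, 99.9). With a summed count of at least 500, fatty acid oxidation and oxidative phosphorylation (0.055) lost their call, the former also after thinning (weakest 0.096). Lower lists were the lysosome (-0.26, percentile 0.01), with Lamp2 at -0.68 and Ctsb at -0.61, antioxidant genes (-0.22, 0.155) and ribosomal proteins (-0.12, 0.115; -0.012 and no longer apart with a summed count of at least 500), while the beta cell identity list (-0.17, 2.25) kept its call under 7 of 14 alternatives. The metal-binding metallothionein genes Mt1 (1030 and 341 CPM, -1.59) and Mt2 (676 and 197 CPM, -1.78) had low ratios, as did AI413582 (-1.30), the calcium-binding Tesc (-1.20) and Crybb3 (-1.63, 30.3% of its chow counts in 5 cells). Genes with high ratios were the immediate early genes Fosb (2.65 on the log2 scale, 157 CPM in the HFD library) and Egr1 (182 and 434 CPM, 1.25), Lztfl1 (1.36) and the arginase gene Arg1 (1.19). The ghrelin gene Ghrl had the highest ratio (7.70), but 5 HFD cells held 99.95% of its counts.

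Delta cells restrain insulin and glucagon release through somatostatin. Sst had 86660 CPM in chow and 63793 CPM in HFD delta-like cells (log2 ratio -0.44). The PP cell markers, Ppy and Pyy among them, took 15.1% and 14.0% of UMIs in these cells, more than the delta cell markers with 9.32% and 6.88%. Of 22 lists in delta-like cells, 7 stood apart below and 4 above. Interferon and antigen presentation stood at -0.35 (percentile 0.00), with B2m at 214 and 120 CPM (-0.83). The unfolded protein response stood at -0.17 (0.13), with Pdia6 at 361 and 214 CPM (-0.75), and the lysosome at -0.18 (0.18), with the protease gene Ctsl at 798 and 579 CPM. The former lost its call with means over cells (-0.085), the latter after thinning and with a summed count of at least 500 (weakest -0.076). Lipid-associated macrophage genes (-0.39), beta cell heterogeneity genes (-0.28), dedifferentiation genes (-0.24) and the cell cycle list with 5 measured genes (-0.49) were lower too, but the dedifferentiation list lost its call under 3 of 14 alternatives (weakest -0.06), and with no minimum count the heterogeneity list lost its call and the cell cycle list stood at 0.0. Cholesterol synthesis stood at 0.25 (percentile 99.9), the mitochondrially encoded list at 0.20 (99.5) and ribosomal proteins at 0.11 (100). Beta cell identity genes stood at 0.29 (100), with Slc2a2 at 6.71 and 14.1 CPM (1.06), but Ins1 and Ins2 made up 3.98% of UMIs in chow and 6.73% in HFD delta-like cells, and neither this list nor the mitochondrially encoded list stood apart once free RNA was subtracted. The mitochondrially encoded list also lost its call with a summed count of at least 500. The insulin receptor substrate gene Irs2 was higher in the HFD library, 16.1 and 50.2 CPM (1.64), as were the immediate early genes Fosb (1.21) and Nr4a1 (1.13), the zinc transporter gene Slc30a8 (1.06) and the secreted Notch ligand gene Dlk1 (1.17, 22.1% of HFD counts in 5 cells). Hspa1a (73.8 and 14.5 CPM, -2.34), the protease inhibitor gene Timp1 (-1.59), Gstp1 (-1.43), Fkbp11 (-1.19) and Ifi27 (-1.14) were lower.

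PP cells secrete pancreatic polypeptide, a hormone of the gut and brain axis. In PP-like cells, 188 in the chow library and 138 in the HFD library, Ppy itself had a log2 ratio of 0.08. Immediate early and heat shock genes stood at 0.51 (percentile 100), with Fosb at 18.7 and 194 CPM (3.36) and Egr1 at 169 and 447 CPM (1.41). Cholesterol synthesis stood at 0.48 (percentile 100), with the isomerase gene Idi1 at 1.56 and Hmgcs1 at 1.39. Mitochondrially encoded genes (0.30; 12 of 12 above) and ribosomal proteins (0.11) were higher as well, the latter no longer apart with a summed count of at least 500 (0.029). Interferon and antigen presentation stood at -0.78 (percentile 0.00), with the antiviral tether gene Bst2 at -1.61, the lysosome at -0.37 (17 of 17 below), with Ctsl at 329 and 207 CPM, and glycolysis at -0.43 in these PP-like cells. Lipid-associated macrophage genes (-0.42) and the tricarboxylic acid cycle (-0.30) were lower, and so was oxidative phosphorylation (-0.09), which kept its call under 10 of 14 alternatives. Iapp (5830 and 2570 CPM, -1.18), the lysosomal sialidase gene Neu1 (-1.12), the immunoproteasome gene Psmb8 (-1.01), Dnajb1 (-1.01) and Hspa1a (-1.91, 35.3% of chow counts in 5 cells) had low ratios. The keratin gene Krt8 (106 and 273 CPM, 1.37), Ccnl1 (1.26) and the flow-responsive factor gene Klf2 (2.62, 60.2% of HFD counts in 5 cells) had high ratios.

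Endothelial cells carry blood through the islet and lay down its basement membrane. In endothelial-like cells, extracellular matrix genes stood at 0.42 (percentile 99.8; 7 of 8 above), with the collagen gene Col4a1 at 506 and 795 CPM (0.65) and Timp3 at 494 and 847 CPM (0.78), and endothelial identity genes at 0.34 (10 of 11 above), with the growth factor receptor gene Kdr at 1084 and 1878 CPM (0.79) and the tight junction gene Cldn5 at 216 and 110 CPM (-0.97). Mitochondrially encoded genes stood at 0.47 (12 of 12 above), and the cell cycle list of 5 genes (0.44) kept its call under 7 of 12 alternatives. Glycolysis (-0.36), the tricarboxylic acid cycle (-0.22), lipid-associated macrophage genes (-0.44), heterogeneity genes (-0.32) and ribosomal proteins (-0.09) were lower in endothelial-like cells. Of these, heterogeneity genes turned under 4 of 14 alternatives (up to 0.29), lipid-associated macrophage genes turned under 1 and lost their call under another, and ribosomal proteins and the tricarboxylic acid cycle lost theirs under 2 each. The delta (-1.98) and alpha (-0.35) identity lists were lower too. With free RNA subtracted the delta list lost its call and the alpha list turned. The alpha list also turned under 1 other of 13 alternatives and lost its call under 2 more, and 5 chow cells held 88.0% of the Sst counts (log2 ratio -3.19), and Pyy (-1.69, 63.2%) likewise came from few cells. The butyrophilin-like gene Btnl9 (42.9 and 167 CPM, 1.95), the phosphatase gene Ptprg (1.53), the taurine transporter gene Slc6a6 (1.47), Fos (153 and 573 CPM, 1.91) and Fosb (3.26) had high ratios. The inflammatory factor gene Cebpb was lower, 193 and 50.5 CPM (-1.92), as were Lrg1 (-2.93) and the adhesion molecule gene Selp (-2.30), for which 5 cells held 68.5% and 91.4% of chow counts.

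Macrophages of the islet clear debris and can release cytokines. In macrophage-like cells, 60 in the chow library and 74 in the HFD library, the immediate early and heat shock list stood at 1.05 (percentile 100; 15 of 17 above), with Egr1 at 40.4 and 166 CPM (2.02). Inflammatory cytokines stood at 0.81 (percentile 100), with the NF-kB inhibitor gene Nfkbia at 304 and 1154 CPM (1.92) and Tnf at 104 and 449 CPM (2.1), while the chemokine gene Ccl5 had 6018 and 1474 CPM (-2.03). With no minimum count this list turned to -0.15. The chemokine gene Cxcl1 (3.40) and the phosphatase gene Dusp2 (2.78) were higher, with 68.0% and 30% of HFD counts in 5 cells, and Tnf had 32.1% in 5 cells. The unfolded protein response (0.34), mitochondrially encoded genes (0.25) and ribosomal proteins (0.11) were higher in macrophage-like cells as well. Interferon and antigen presentation stood at -0.65 (percentile 0.00), with Irf7 at -2.31, antioxidant genes at -0.35, with the peroxiredoxin gene Prdx1 at 7325 and 3113 CPM (-1.23), glycolysis at -0.43 and the lysosome at -0.29. Secretory granule genes (-0.31), heterogeneity genes (-0.59) and alpha identity genes (-1.80) were lower, but 5 chow cells held 89.4% of the Gcg counts (log2 ratio -3.80), and the same held for Ttr (-3.36), Pyy (-3.19), Sst (-2.82) and Ppy (-2.44), each with 81.2% or more in 5 cells. The heterogeneity list lost its call under 3 of 13 alternatives (weakest -0.39), and secretory granule genes and the lysosome lost theirs after thinning. Mgp (5.77) and Krt8 (3.19) likewise came from few HFD cells, 98.7% and 100% in 5 cells. The insulin genes made up 5.90% and 6.46% of UMIs in macrophage-like cells, so RNA of other cells was present in both libraries.

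CD63 sits in the membranes of lysosomes and secretory vesicles and is found in many cell types, so its level in beta cells was read beside that of other islet cells. Cd63 was lower in the HFD library in each of the 6 types: 687 and 364 CPM in alpha-like cells (log2 ratio -0.92), 2165 and 1522 CPM in delta-like cells (-0.51), 845 and 426 CPM in PP-like cells (-0.99), 297 and 157 CPM in endothelial-like cells (-0.92) and 3069 and 2496 CPM in macrophage-like cells (-0.30). In beta-like cells the ratio of the summed counts was -1.56 before subtraction of the median (interval -1.58 to -1.53), but these sums mix clusters that the libraries filled unequally. Within the 5 shared beta-like clusters it was -0.41, -0.39, -0.42, -1.05 and -0.61 in clusters 0, 2, 3, 6 and 7, in 4 of 5 closer to 0 than in alpha-like, PP-like and endothelial-like cells. At a common depth of 4000 UMIs, 86.4% of chow and 62.7% of HFD beta-like cells had at least 1 Cd63 UMI, against 55.0% and 30.4% of endothelial-like cells, the type with the lowest level, where free RNA adds to the count. Before thinning, median depths were 14565 and 16502 UMIs in beta-like and 7268 and 6772 UMIs in endothelial-like cells. Delta-like cells had a Cd63 UMI in 100% and 99.8% of cells.

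**Figure D3:**
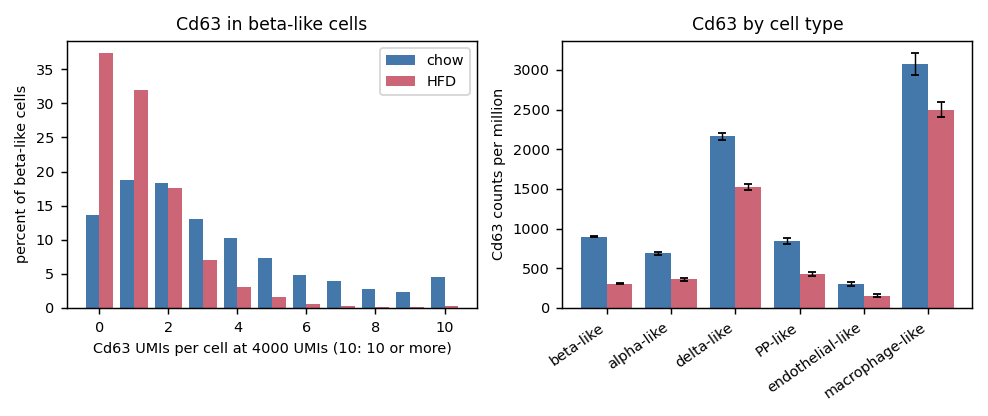
Left, percent of beta-like cells by Cd63 UMIs per cell at 4000 UMIs in each library, the last bin holding cells with 10 or more; right, Cd63 CPM by cell type and library as bars with exact Poisson 95% intervals. Cells with no Cd63 UMI made up 13.6% of chow and 37.3% of HFD beta-like cells.

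CD63 lies on the vesicles through which beta cells move and degrade their cargo, and the study asked what sets beta cells with high CD63 apart from those with low CD63. Cd63 counts per cell formed a continuous range, so high and low are parts of that range and not cell types. The level also differed between clusters. In the chow library Cd63 had 367, 295, 440, 767 and 596 CPM in clusters 0, 2, 3, 6 and 7. Each value lay below that of all chow beta-like cells, so the remaining chow cells, mostly in clusters 1, 5 and 8, lay higher. The split was not repeated within clusters, so traits of Cd63-high cells may be traits of clusters. Cells with at least 5 Cd63 UMIs at 4000 UMIs made up 25.8% of chow beta-like cells (1127 of 4367), as set by the definition, and 3.07% of HFD beta-like cells (92 of 2994, 2.48 to 3.76%). Cells with at most 1 Cd63 UMI made up 32.4% (1416 cells) and 69.3% (2074 cells, 67.6 to 70.9%). The mean Cd63 count was 3.30 and 1.20, and 22.5% of chow and 5.21% of HFD beta-like cells lay within 1 count of the bound for high cells. With each library's own percentiles, 2 counts or more were high in the HFD library and made up 30.7% of its cells. Cd63-high cells had a median of 1495 and 1434 Ins2 UMIs, 3 and 2 Gcg UMIs, 0 and 0 Sst UMIs and 5 and 4 Ppy UMIs, and 38 of 1127 chow and 5 of 92 HFD cells among them had at least 3 Sst UMIs, against 52 of 1416 and 36 of 2074 Cd63-low cells. Before thinning, Cd63-high cells were deeper than Cd63-low cells in the chow library (medians 17574 and 12844 UMIs) and shallower in the HFD library (12603 and 16501).

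Beta cells couple fuel use to secretion, and the question was whether genes of metabolism and identity go with Cd63 among single cells. In the chow library, Cd63-high cells had more nuclear-encoded oxidative phosphorylation (median log2 ratio of high over low 0.40, 66 of 76 genes higher), glycolysis (0.61, 10 of 12) and antioxidant genes (0.48, 16 of 19) and less of the beta cell identity list (-0.39, 20 of 22 lower). Each of these 4 medians lay beyond those of all 100 splits by control genes of like expression, whose extremes were 0.34, 0.41, 0.37 and -0.25. In the HFD library, with 92 Cd63-high cells, oxidative phosphorylation (0.55, 71 of 76 higher) and antioxidant genes (0.59) exceeded 99 of 100 control splits, and beta cell identity (-0.22, 19 of 22 lower) lay below all but 1. Antioxidant genes lost their call with the 90th and 10th percentiles (percentile 80.5 among random lists). Glycolysis had a median of 0.40 in the HFD library, above 98 control splits but within the range of random lists. The control genes were matched to the Cd63 mean over both libraries (2.45 UMIs), not to that of either library (3.30 and 1.20). With cuts taken from chow, their HFD splits need not hold a like share of cells, so the HFD ranks are not a matched comparison. Many control genes encode ribosomal proteins, and some, such as Cox8a and Atp5l, belong to the oxidative phosphorylation list. Gapdh stood at 1.55 in the chow and 1.26 in the HFD library, uncertain because of its pseudogenes, Aldoa at 1.00 and 0.87, Cox5a at 0.92 and 1.35, Txn1 at 0.91 and 1.21, and Pax6 at -0.51 and -0.33. In the chow library interferon (0.35), the lysosome (0.24), lipid-associated macrophage genes (0.33), immediate early and heat shock genes (0.46) and inflammatory cytokines (0.93) were higher in Cd63-high cells but not beyond all control splits, and the lysosome and macrophage lists kept their call under 6 of 10 alternatives, while interferon turned at 2000 UMIs. Inflammatory cytokines lost their call under 1 of 6 alternatives, with hormone genes left out. The tricarboxylic acid cycle was also higher there (0.12, above 65 control splits) and kept its call under 7 of 10, and mitochondrially encoded genes were lower in 12 of 12 (-0.31). In the HFD library the mitochondrially encoded list stood at -0.09 (9 of 12 lower), but it turned with no cell filter and lost its call with that library's own percentiles. In the HFD library interferon stood at 0.74, delta identity at 1.67, secretory granule genes at -0.10 and the unfolded protein response at -0.14. Of 10 alternatives, the call was lost under 2 for interferon (1 of them the omission of the Ppy-bearing clusters, which also removes the interferon-led cluster 13), 1 for delta identity (hormone genes left out, median 0.11), 3 for secretory granule genes and 5 for the unfolded protein response. The tricarboxylic acid cycle stood at -0.26 in the HFD library, opposite to the chow library, but it turned under 4 of 10 alternatives and lost its call under 4 more.

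Fkbp11, Tspan8 and Folr1 encode a folding enzyme, another tetraspanin and a folate receptor, and Tspan8 and Folr1 are also markers of PP cells. Higher in Cd63-high cells of both libraries were Fkbp11 (1.56 in chow, 2.41 in HFD), Tspan8 (1.20 and 2.41), Folr1 (1.23 and 2.13), the proteasome gene Psmc5 (1.20 and 1.99), the thioesterase gene Acot13 (1.32 and 1.75), the ribonuclease inhibitor gene Rnh1 (1.36 and 1.47) and the matrix protein gene Spp1 (2.26 and 1.81). Lcn2 stood at 3.17 and 1.99, with an interval from -3.97 to 4.40 in the HFD library. In a second random draw of the thinning the HFD ratio of Spp1 was -0.13, and without the Ppy-bearing clusters that of Folr1 was -0.79. Summed counts of hormone genes of other cells were also higher, with Sst at 0.70 and 3.34, Pyy at 0.70 and 2.96, Ppy at 0.82 and 2.33 and the retinol carrier gene Rbp4 at 0.15 and 3.49, and without the Ppy-bearing clusters the HFD values were 2.95, 0.90, 1.23 and 2.18. The median cell did not differ in this way. Ppy had medians of 5 and 4 UMIs and Pyy of 2 and 2 in both Cd63-high and Cd63-low cells. Sst had medians of 0 and 0 in Cd63-high and of 1 and 0 in Cd63-low cells, so the higher sums came from a part of the cells. Lower in Cd63-high cells were Slc2a2 (-0.96 and -0.95), the insulin receptor-related gene Insrr (-0.78 and -1.19), the oxidoreductase gene Ero1lb (-0.75 and -1.34), the calcium pump gene Atp2a3 (-0.77 and -1.17), the ubiquitin ligase gene March6 (-0.77 and -1.23) and the chromatin remodeller gene Smarca4 (-0.47 and -1.61). Syndig1l, Phactr1, Glg1, Twsg1, Gdap1 and Runx1t1 were lower in both libraries as well. Across 1743 genes, which are not independent replicates, 1212 had the same sign in both libraries and Pearson's r across genes was 0.68. The lower oxidative phosphorylation of HFD beta-like cells remained, at a smaller size, among cells with equal Cd63 counts. At counts of 0, 1, 2 and 3, the list difference between libraries was -0.27, -0.22, -0.32 and -0.28, against -0.43 over all thinned cells. Counts this low measure the Cd63 level of a cell with error, so whether Cd63 make-up accounts for the difference cannot be decided.

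**Figure D4:**
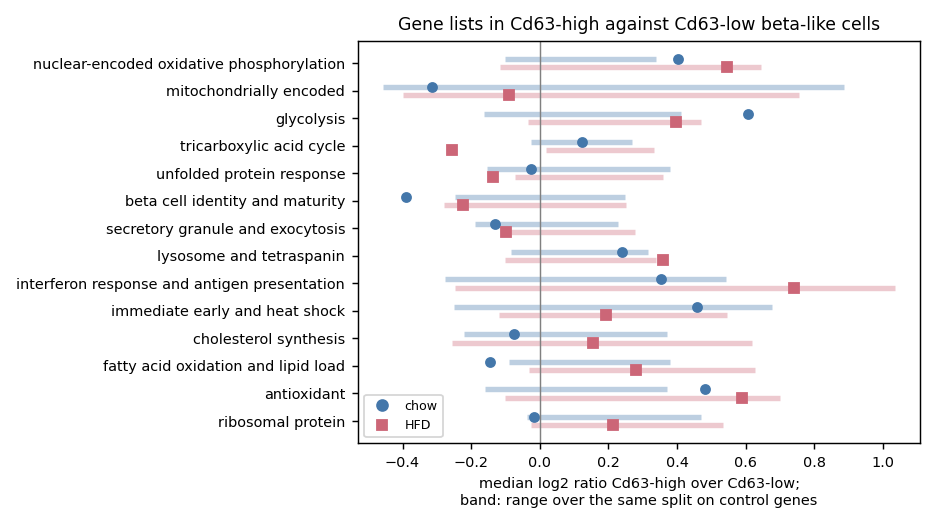
Median log2 ratio of Cd63-high over Cd63-low beta-like cells for gene lists, with circles for the chow library, squares for the HFD library and bands for the range over 100 splits by control genes. In the chow library oxidative phosphorylation (0.40) lay above its band and beta cell identity (-0.39) below.

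Adult beta cells seldom divide, and high-fat feeding can raise their proliferation. Cells with UMIs of at least 2 of 12 mitotic genes, such as Mki67, Top2a and Cdk1, made up 0.229% of chow beta-like cells (10 of 4367, 0.110 to 0.421%) and 0.234% of HFD beta-like cells (7 of 2994, 0.0941 to 0.481%) at 4000 UMIs. A difference was not detectable at this depth. The background in other types was 0 of 463 chow delta-like cells, which allows a share of up to 0.648%, and 1 of 403 HFD delta-like cells (0.248%), with median depths of 8041 and 9604 UMIs before thinning. Among endothelial-like cells, 0 of 180 chow cells (up to 1.67%) and 0 of 125 HFD cells (up to 2.40%) met the rule. Among alpha-like cells 0 of 710 chow cells (up to 0.423%) and 0 of 389 HFD cells (up to 0.771%) did. Among PP-like cells these were 0 of 188 (up to 1.60%) and 0 of 138 (up to 2.17%). Macrophage-like cells had 0 of 59 in the chow library (up to 5.08%) and 1 of 74 in the HFD library (1.35%, 0.0342 to 7.30%). With at least 3 of the 12 genes, 9 chow and 4 HFD beta-like cells met the rule, against 0 and 0 in each of the 5 other compared types. Cluster 15, led by cell cycle genes, held 13 chow and 10 HFD beta-like cells, while the intervals of the shares overlapped between types.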

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

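The tests of the patterns in this part were chosen only after the results had been seen. Some gene lists that stood apart in beta-like cells stood apart the other way in another type, and these differences between types were not tested. Ribosomal protein genes, with a list difference of 0.13 in beta-like cells, stood at -0.12 in alpha-like cells (-0.012 with a summed count of at least 500) and -0.086 in endothelial-like cells; the difference was not tested. The unfolded protein response stood at -0.32 in beta-like cells against 0.19 in alpha-like and 0.34 in macrophage-like cells; the difference was not tested. The chaperone genes Hspa5 and Hsp90b1 had log2 ratios, relative to the all-gene median, of -0.48 and -0.73 in beta-like cells and of 0.46 and 0.56 in alpha-like cells.

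Nuclear-encoded oxidative phosphorylation genes were lower in HFD beta-like cells (list difference -0.42, 76 of 76 genes below the all-gene median), whereas in alpha-like cells the list stood at 0.089; the difference was not tested. This value in alpha-like cells argues against an equally lower yield of these transcripts in the whole HFD library, although the list also lay below random lists in PP-like cells (-0.09). Under the alternatives it stood at -0.060 to -0.012 in delta-like, -0.075 to -0.021 in macrophage-like and 0.0069 to 0.056 in endothelial-like cells. The alpha-like list lost its call with a summed count of at least 500 (0.055). In beta-like cluster 0 the difference was only -0.07, so a smaller loss of yield is not excluded. With every cell at 4000 UMIs the difference in beta-like cells was -0.42, which argues against the greater weight of deep cells in the sums as the cause. Random thinning keeps the composition of each cell, so this test cannot decide on other effects of depth. The list lay below random lists in 5 of 5 shared beta-like clusters, which argues against cluster make-up as the whole cause, although the median there was -0.16 and a part of the difference may come from it. Clusters 1, 5 and 8, with many chow but few HFD cells, are outside this check. With 1 library per diet, library preparation and diet cannot be told apart, and a lower respiratory gene program of beta cells under the diet stays a hypothesis.

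Cd63 was lower in the HFD library in each of the 6 compared types. The counting interval of its ratio in 5 of 5 other types lay wholly above that of all beta-like cells. This contrast is uncertain, since the ratio was -0.39 to -0.61 in 4 of the 5 shared beta-like clusters and -1.05 in the other. Both libraries were clustered together without integration, so a difference between the libraries can itself set clusters apart. Cluster make-up and a difference within cells therefore cannot be separated here. Among the other types the interval in macrophage-like cells (-0.38 to -0.21) lay wholly above that in PP-like cells (-1.10 to -0.88). These types had the highest and the lowest ratio of the other types, and the intervals hold no spread between cells or mice. Whether 1 equal loss of signal in every cell is the whole cause can therefore not be decided from them. After subtraction of free RNA the log2 ratio in alpha-like cells was -0.90 against -0.92 before, which argues against free RNA from beta-like cells as its source there. An equal loss of signal, a difference in preparation that acts on cell types unequally and an effect of the diet on lysosomes and vesicles all remain possible explanations. With 1 library per diet these cannot be told apart.

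Immediate early genes such as Fosb, Egr1 and Fos, which respond within minutes to stimulation, were higher in the HFD library, while heat shock genes such as Hspa1a were mostly lower. A few cells with very high counts are argued against, since 44.2% of HFD PP-like cells (35.8 to 52.9%) had a Fosb UMI at 4000 UMIs, against 5.85% of chow PP-like cells (2.96 to 10.2%). Heat shock members had a median below the all-gene median in 4 of 6 types, from -1.30 in beta-like cells to 0.19 in macrophage-like cells, so 1 stronger dissociation stress response may still account for the alpha-like and macrophage-like types, where both medians were higher. Against it in alpha-like cells, 2 of 5 heat shock members lay below, and 8.59% of chow (6.64 to 10.9%) but 0.257% of HFD cells (0.00651 to 1.42%) had an Hspa1a UMI. Immediate early members had a median above it in 5 of 6 types, with the sums of beta-like cells the exception (-0.17). Within the 5 shared beta-like clusters, however, the list of immediate early and heat shock genes had list differences of 0.03 to 0.48. Since the labels give 1 protocol with culture overnight and no date, time or handling of the cells and diet cannot be told apart.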

How the results depend on the processing

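Leaving out clusters, using cluster 0 alone and the second draw of the thinning were chosen only after the results had been seen. No paired analysis was possible because each diet has 1 library and no cell is tied to a mouse. For the same reason no replicate was left out, and the values below show dependence on the processing, not on the animals. Depth limits what can be said about genes near the floor, such as Mafa and Aldh1a3 in beta-like cells, about mitotic genes, and about Cd63-high cells of the HFD library, which number 92. Values for lists are list differences and those for genes log2 ratios before subtraction of the median. Where the construction does not show it, the cause was not tested.

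Of 72 shares of cell types under alternatives, 59 stayed within their interval and 13 moved. Under the stricter cell filter the shares were 69.2% chow and 67.2% HFD for beta-like, 8.78% and 10.8% for delta-like, 10.3% HFD for alpha-like, 3.74% chow for PP-like and 3.59% chow for endothelial-like cells. With no doublets removed, beta-like cells made up 70.6% of the chow library and delta-like cells 6.97% and 8.53%. At resolution 2.0 beta-like cells made up 61.4% and 63.6%, and with each library clustered on its own 71.8% of the chow and 63.8% of the HFD library, with separate intervals, since clusters with mixed markers then stayed unnamed. With at least 1 mitotic gene, cycling cells made up 0.939% and 1.40%, a looser rule by construction.

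Of the beta-like list results under alternatives, the number of lists apart counted among them, 376 stayed as reported. Another 23 gained a call, 5 lost one and 1 turned, and the number of lists apart moved under 2. For single genes in beta-like cells, 290 ratios stayed within their counting interval, 156 left it and 2 turned, alternatives of scaling included. Oxidative phosphorylation (-0.43 to -0.07), the unfolded protein response (-0.36 to -0.20) and ribosomal proteins (0.07 to 0.16) kept their side of the limits under 16 of 16. Alternatives that change the scaling only are among these and could hardly move a list. In cluster 0 alone, which removes differences in cluster make-up, glycolysis turned to 0.0052, and interferon (-0.14), mitochondrially encoded (0.050) and sex-linked genes (0.10) no longer stood apart, while heterogeneity (-0.27), cholesterol synthesis (-0.13), delta identity (-0.28) and fatty acid oxidation (0.22) did. There 12 of 24 named genes were named again, and Slc2a2 (-0.16) and Ins2 (0.077) took the other sign. Thinning left the mitochondrially encoded list at 0.20, within the limits, and set the cell cycle (-0.51) and inflammatory cytokines (-1.06) apart. With no minimum count the sex-linked list (0.24), then with Xist counted in, lost its call and the cell cycle (-0.24) gained one. Without the Ppy-bearing clusters 12 lists stood apart, with heterogeneity at -0.28, beta identity at 0.23, dedifferentiation at -0.56, delta identity at -0.53 and inflammatory cytokines at -0.44. Each library clustered on its own gave 11 lists apart, with heterogeneity at -0.32, beta identity at 0.22, dedifferentiation at -0.59 and endothelial identity at -0.38. Resolution 2.0 set apart heterogeneity (-0.26), dedifferentiation (-0.45) and delta identity (-0.59). Delta identity also stood apart without the interferon and cell cycle clusters (-0.57), inflammatory cytokines with means over cells (-0.69), and beta identity under the stricter filter (0.22) and with a summed count of at least 500 (0.20).

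In the other types, 1321 results for single lists and genes stayed as reported, 95 moved, 42 lost their call and 13 turned. These counts leave out lists that did not stand apart at first, some of which gained a call or turned. Beta cell identity in endothelial-like cells, for instance, gained a call under 2 and turned under 2 of 14 alternatives (-3.31 to 0.63). A summed count of at least 500, which leaves fewer genes, gave 0.0021 for oxidative phosphorylation in PP-like cells, 0.083 for beta identity in alpha-like cells and 0.0 for heterogeneity in endothelial-like cells, with 6 lists apart in each of PP-like and endothelial-like cells. In endothelial-like cells resolution 2.0 gave 0.26 for alpha identity and 0.14 for heterogeneity with 7 lists apart, thinning gave 0.29 for heterogeneity with 7 lists apart, and separate clustering gave 0.012 for lipid-associated macrophage genes. Subtraction of free RNA gave 0.51 for alpha identity, 0.14 for heterogeneity and 0.46 for Pyy in these cells. With no minimum count the cell cycle list in delta-like cells stood at 0.0 and inflammatory cytokines in macrophage-like cells at -0.15. With hormone genes left out of the total, Ppy in PP-like cells stood at -0.000738. Of the 10 genes named in a type, those named again in PP-like cells were 6 under the stricter filter, 5 with no doublets removed and 4 after thinning. In endothelial-like cells they were 6 with no doublets removed, 5 at resolution 2.0, 6 after thinning and 3 with free RNA subtracted, and in macrophage-like cells 6 after thinning.

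For the Cd63 comparison, 16 shares moved, most of them under alternatives that change the definition itself. Of results for single genes and most lists, 621 stayed, 128 moved, 28 lost their call, 9 gained one and 14 turned. At 2000 UMIs the high share was 41.7% chow and 13.3% HFD and the low share 60.4% HFD, and with hormone genes left out first the high share was 27.9% chow and the low shares 26.8% chow and 62.4% HFD. With the 90th and 10th percentiles the high shares were 13.6% and 0.902% and the low shares 13.6% and 37.3%. With percentiles within each library the HFD shares were 30.7% high and 37.3% low. The stricter filter gave 27.2% high and 30.6% low in chow, the second draw 34.0% low in chow, and omission of the Ppy-bearing clusters 2.43% high in HFD. In the HFD library, the tricarboxylic acid cycle turned to 0.063 at 2000 UMIs, 0.069 without hormone genes, 0.034 with the 90th percentile and 0.057 within the library. Mitochondrially encoded genes turned to 0.22 with no cell filter and stood at -0.041 within the library, and immediate early and heat shock genes stood at -0.11 there. Heterogeneity genes turned to 0.77 (HFD) and 0.37 (chow) in the second draw and 0.81 (HFD) at 2000 UMIs, where chow interferon stood at -0.066. Among genes, Spp1 in HFD was -0.13 in the second draw and -0.059 within the library, Folr1 in HFD -0.79 without the Ppy-bearing clusters, and at 2000 UMIs Glg1 in chow was 0.070 and Phactr1 in HFD 0.078.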

Other observations

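The share of cells with a Fosb UMI at 4000 UMIs was higher in the HFD library in each of the 6 compared types. It was 8.73% of chow and 42.7% of HFD cells in the alpha-like type, 13% and 26.3% in the delta-like type and 3.33% and 17.6% in the endothelial-like type. Among macrophage-like cells 6.78% and 27.0% had a Fosb UMI, and among beta-like cells 8.86% and 14.9%. No explanation for the differences between types was tested.

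Lcn2 had a UMI in 7 of 7 chow and 17 of 19 HFD ductal-like cells at 4000 UMIs. Among beta-like cells 1.40% of chow and 0.334% of HFD cells had one. The ghrelin gene Ghrl reached 1208 counts in a single HFD cell of the alpha-like group, and 2 of 389 cells of that group had a Ghrl UMI at 4000 UMIs.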
